A study of Mus musculus with 9 samples.

How the data were processed

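RNA was measured in 9 samples of 1 mouse organoid line, 3 in each of 3 groups that were taken from the sample titles: doxycycline kept, doxycycline removed for 2 days and doxycycline removed for 7 days. Per the labels' protocols, organoids were cultured after a published method for this Apc model, RNA was isolated with a PureLink kit, and poly(A) libraries were made with the NEBNext Ultra II RNA kit, which in this form does not mark the strand. Reads from a gene and from an overlapping or antisense partner therefore cannot be told apart, and counts of near-identical gene copies are uncertain.

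The authors deposited 1 table of raw counts, whole numbers of reads per gene, for all 9 samples. Per the submitters' processing notes, the tools used were STAR 2.7.0e, featureCounts and DESeq2, with mouse genome builds mm10 and GRCm38. The annotation release, the strand setting and any gene filter are not given in the sources used here. The table held 21253 Ensembl gene IDs, of which 21236 were found in GENCODE M21 (GRCm38), 20904 of them protein-coding and 332 of another type. The 17 others were kept under their ID, 30 IDs had a symbol shared with another ID, and 2968 genes had 0 counts in every sample. Coordinates, symbols and GC content were taken from that annotation. Muc2 and Muc3 were not analysed here.

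Totals ran from 24143589 to 32277040 counts per sample, and 14925 to 15574 genes had a count. A group at 0 counts was set at 3 counts over the group to give a bound, and genes with 1 to 3 counts were given as ratios with 95% exact counting intervals, both for counting error only. Each pair of replicates was checked for being 1 library deposited more than once by a chi-square of their counts over genes with at least 10 counts.

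Counts were filtered with filterByExpr, which kept 12535 genes, scaled with TMM factors (1.073 to 1.125 in controls, 1.093 to 1.117 at 2 days and 0.785 to 0.874 at 7 days) and tested in edgeR 4.0.16 under R 4.3.3. The quasi-likelihood model (glmQLFit, glmQLFTest) held all 9 samples and the group alone, so the comparisons shared 1 estimate of the spread (common dispersion 0.00723). Genes were called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. The SE of a log2 fold change was its absolute value over the square root of the F statistic. For large changes with few counts in a group, an SE of this form can lie below counting error. TMM assumes that most genes keep their level, and 82.3% of genes were called at 7 days, so other scalings were run.

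The gene lists, the tests, the rule for named genes and the alternatives were chosen before the data were examined, except where the text says otherwise. There were 29 lists, covering Wnt targets, intestinal cell types, cell cycle phases, signalling and stress pathways, metabolism, ribosome production and 3 cell types outside the epithelium. The 26 with at least 5 tested members were compared with all other genes by camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, adjusted over the 26 lists. Each was repeated with an estimated correlation and with fry, which tests whether the members move, on balance, one way. Counts adjusted over the list alone used the same edgeR p-values, adjusted within the list. The list sizes given with the results are of the members that passed the filter.

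The named genes were 14 markers fixed in advance, of which Muc2 is left out, and those with the largest changes: 10 in each direction against control and 5 in each direction between 7 and 2 days. These had to have an adjusted p under 0.05, at least 5 CPM in the higher group, no overlap between the groups' samples and a symbol other than of a predicted gene or pseudogene. Up to 4 members per list with the smallest p, and for cell types outside the epithelium the 3 with the highest mean CPM, were added. Some genes that the rule takes are not reported here.

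The testing code was run on counts simulated for every group from the control means and the real library sizes. In each run 200 genes expressed in controls were changed up or down. Of the 67 changed by 1.5-fold the code recovered 82.1% for each comparison with controls and 85.1% for 7 against 2 days. It recovered 100% of the 67 changed by 2-fold and of the 66 changed by 4-fold in each. Of its calls 4.08%, 4.08% and 6.4% were of genes simulated without change. These ran on 11951, 11958 and 11944 genes. With so few genes changed, they do not test the scaling or the false calls where 82.3% of genes are called, as at 7 days.

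The alternatives were DESeq2 size factors, library size alone or upper-quartile factors in place of TMM, no filter or a mean of at least 5 CPM, limma-voom, the DESeq2 1.42.0 Wald test, glmTreat against a log2 fold change of 1, only the 2 groups compared, the replicate number as a block, thinning to the smallest library and leaving out each sample in turn. After the data had been seen, a run without the 100 most abundant genes and 2 forms of removing a smooth GC trend were added; 99.82% of the tested genes had a GC value.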

Results

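Gene expression was measured by RNA sequencing in 9 samples of mouse AKP tumour organoids (tumoroids), 3 in each of 3 groups. As background, Apc encodes an inhibitor of the Wnt pathway that is often lost in intestinal tumours, and Trp53 encodes the p53 tumour suppressor. In this culture Apc is silenced by a short hairpin RNA that needs doxycycline, so that taking doxycycline away restores Apc. Control samples stayed in doxycycline with Apc off, and the other groups were collected 2 days and 7 days after doxycycline had been removed. The comparisons ask which genes differ once Apc has been restored for each of these times. Doxycycline removal and Apc restoration coincide in every sample, and the labels call the replicates technical, so p-values measure only the spread between these samples, which may be technical. Both times were compared with the same controls, so time in culture is not separated from doxycycline removal or Apc restoration either.

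The libraries held 24143589, 32153755 and 25045752 counts in the controls. The totals were 29899796, 26108855 and 29172358 at 2 days and 29445507, 32277040 and 31237403 at 7 days. Levels below are CPM (counts relative to the TMM-scaled library total), as mean ± SD with n = 3. Changes are log2 fold changes (log2FC) ± SE, which can be too small where a group has few counts. The 10 most abundant genes took 6.25% to 7.11% of the counts in controls, 6.31% to 6.8% at 2 days and 12% to 13.8% at 7 days. Near-identical copies of Sprr2a, an epithelial envelope gene whose counts are uncertain for that reason, took 0.335% to 0.369%, 0.835% to 0.86% and 6.32% to 7.25%. Replicates of a group had Spearman correlations across genes of 0.9931 to 0.9986, and the chi-square of their counts per degree of freedom was 4.24 to 38.3, above sampling noise for every pair. The first principal component held 91.6% of the variance, with controls at −76.6 to −73.1, 2-day samples at −43.5 to −41.4 and 7-day samples at 115.7 to 120.3.

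Apc (ENSMUSG00000005871, GRCm38 chromosome 18, 34220924 to 34322552, plus strand), the gene the hairpin targets, was read first in every sample. It stood at 6.8, 6.8 and 8.8 CPM in the controls, 31.8, 38.1 and 24.8 CPM at 2 days, and 67.9, 69.9 and 92.9 CPM at 7 days. The means were 7.49 ± 1.17, 31.6 ± 6.66 and 76.9 ± 13.9 CPM (SD, n = 3), so each group's samples lay above all samples of the group before it. The rise was 4.22-fold at 2 days (log2FC 2.08 ± 0.17, edgeR adjusted p = 3.1e-07) and 10.3-fold at 7 days (3.36 ± 0.17, edgeR adjusted p = 6.2e-11). From 2 to 7 days Apc rose a further 2.44-fold (edgeR adjusted p = 1.3e-06). Trp53 counts were low throughout, at 2.93 ± 0.326, 2.79 ± 0.435 and 1.17 ± 0.266 CPM, and the fall at 7 days passed the test (log2FC −1.33 ± 0.20, edgeR adjusted p = 1.7e-05).

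**Figure D1:**
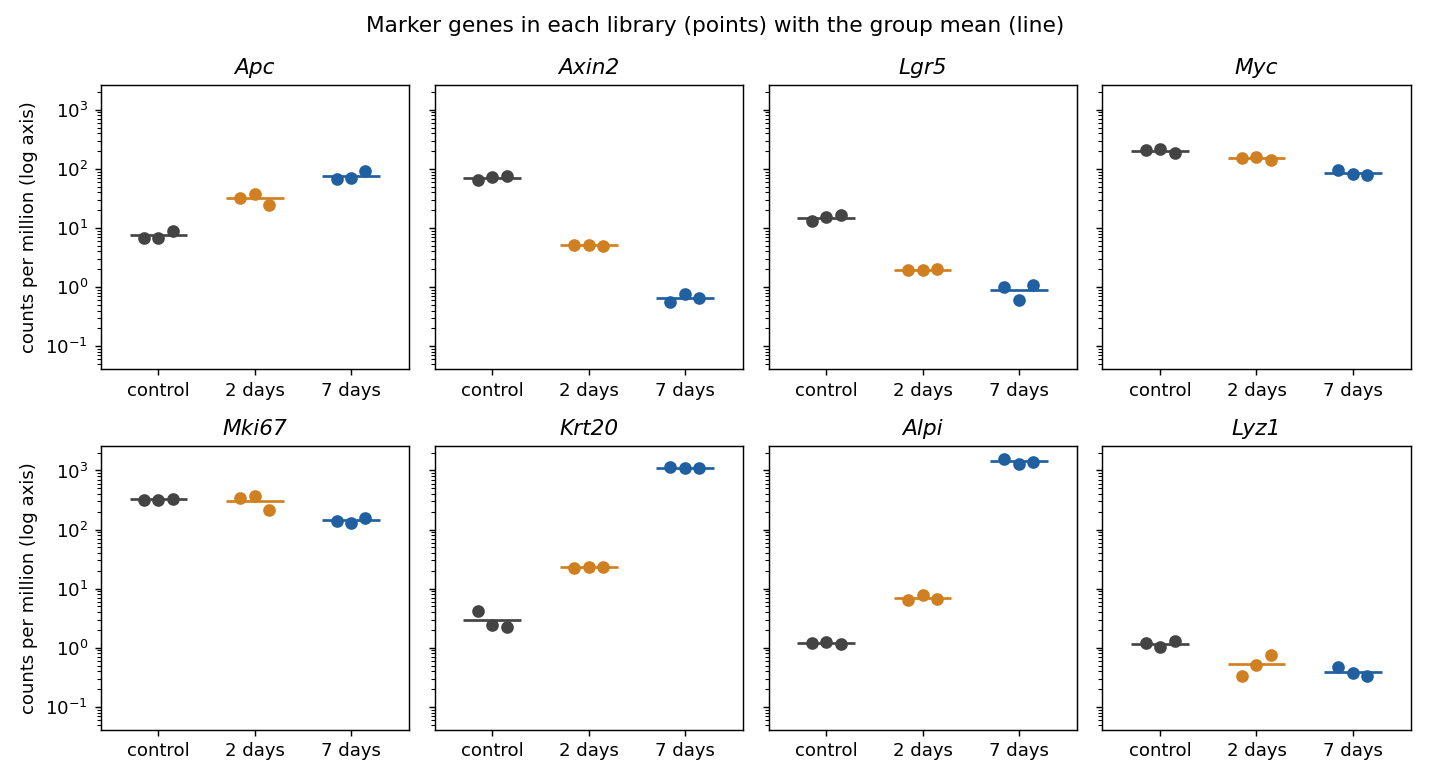
Expression of 8 marker genes in each library, in CPM on a log axis, for control, 2-day and 7-day samples; points are single libraries and lines are group means (n = 3). Apc rises from a mean of 7.49 to 76.9 CPM and Krt20 from 2.95 to 1110 CPM, while Axin2 falls from 70.5 to 0.658 CPM.

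After 2 days without doxycycline, Wnt target and stem cell genes fell together and markers of mature intestinal cells began to rise. Axin2 (ENSMUSG00000000142, GRCm38 chromosome 11, 108920349 to 108950783, plus strand), a feedback target of Wnt signalling, fell from 70.5 ± 5.05 to 5.1 ± 0.0809 CPM (log2FC −3.79 ± 0.10, edgeR adjusted p = 2.7e-12). Ascl2 (ENSMUSG00000009248, chromosome 7, 142966829 to 142969264, minus strand), a transcription factor of crypt-base stem cells, fell from 18.1 ± 1.62 to 0.95 ± 0.11 CPM (−4.25 ± 0.15, edgeR adjusted p = 1.2e-10). Lgr5 (ENSMUSG00000020140, chromosome 10, 115450311 to 115587780, minus strand), the R-spondin receptor that marks these cells, fell from 14.9 ± 1.74 to 1.96 ± 0.0611 CPM (−2.93 ± 0.15, edgeR adjusted p = 1.8e-09). Krt20 (ENSMUSG00000035775, chromosome 11, 99428403 to 99438150, minus strand), a keratin of differentiated epithelium, rose from 2.95 ± 1.09 to 23 ± 0.456 CPM (2.98 ± 0.16, edgeR adjusted p = 3.2e-09).

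Of the 19 Wnt targets tested at 2 days, 17 fell and 1 rose, with the same counts adjusted over the list alone. Tnfrsf19 fell 12.2-fold from 111 to 9.05 CPM, Sp5 fell 10.2-fold, and Tcf7 dropped from 73.1 to 14 CPM; the riser was Apcdd1 (log2FC 0.33), named after its value was seen. The list fell against all other genes (camera adjusted p = 1e-15). Of 15 crypt-base stem cell markers 11 fell, 12 when adjusted over the list alone, among them Smoc2 from 95.6 to 27.2 CPM (camera adjusted p = 2.1e-10). Other genes with the largest falls were Wnt6 (12.1-fold), Rgcc (12.4-fold), Ptpro (9.31-fold) and Dach1 (8.63-fold). The beta-globin genes Hbb-bs (ENSMUSG00000052305, chromosome 7, 103826534 to 103828096, minus strand; 12.1 ± 1.37 to 0.687 ± 0.105 CPM) and Hbb-bh1 (8.96 ± 1.19 to 0.804 ± 0.126 CPM) were also among the 10 largest falls. The oncogene Myc fell 1.36-fold, from 204 ± 15.2 to 150 ± 7.47 CPM (log2FC −0.44 ± 0.09, edgeR adjusted p = 0.0015).

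Goblet cell markers and part of the enterocyte and colonocyte markers rose at 2 days. Dmbt1 (ENSMUSG00000047517, chromosome 7, 131032053 to 131121630, plus strand), a secreted mucosal scavenger receptor, showed the largest rise under the rule for named genes, from 4.54 ± 1.13 to 66.6 ± 10.1 CPM (log2FC 3.86 ± 0.16, edgeR adjusted p = 4.2e-10). Tmem236 (11.5-fold), Fam3b (9.54-fold), Sptssb (9.52-fold), Adamts15 (7.06-fold) and the intestinal cholesterol transporter Npc1l1 (6.72-fold) were also among the 10 largest rises. Of 17 goblet cell markers, 14 rose and 1 fell (15 and 1 adjusted over the list alone; camera adjusted p = 9.4e-11), including Zg16 (9.17-fold), Clca1 (8.6-fold), Tff3 (10.9 to 63.6 CPM) and Fcgbp (18.9 to 84 CPM). Of 28 enterocyte markers 8 rose, with the same count adjusted over the list alone (camera adjusted p = 1.3e-05). They included Alpi (ENSMUSG00000079440, chromosome 1, 87098002 to 87101606, minus strand), the intestinal alkaline phosphatase, from 1.2 ± 0.0313 to 6.99 ± 0.692 CPM, and Mep1b from 15.1 to 37.5 CPM. Of 14 colonocyte markers 6 rose, and 7 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0014), with Lypd8 up 7.07-fold and Emp1 from 598 to 975 CPM. Fabp1, an enterocyte fatty acid carrier, had 3 counts over the controls and 3 over the 2-day samples, so no ratio is given.

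Only 6 of the 18 Paneth cell markers listed passed the expression filter, and most of these fell at 2 days. The tested members were also few for tuft cells (5 of 18 listed) and enteroendocrine cells (4 of 23). Of 6 Paneth cell markers 4 fell and 1 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.021, but adjusted p = 0.25 with an estimated correlation and 0.056 with the replicate number as a block in the camera test). Itln1 fell from 21.6 to 4.8 CPM, Pla2g2a from 6.64 to 0.51 CPM and Mmp7 from 4.32 to 1.24 CPM, while Reg4, a peptide of secretory cells, rose from 1.99 to 4.22 CPM. The lysozyme gene Lyz1 fell from 1.17 ± 0.125 to 0.541 ± 0.216 CPM (edgeR adjusted p = 0.0068). Of 5 tuft cell markers 2 fell, also adjusted over the list alone, Ptgs1 from 133 to 35.9 CPM and Pou2f3 from 0.605 to 0.0844 CPM, and the other 3 did not pass in edgeR, though limma-voom called 1 of them higher. The tuft list's call (camera adjusted p = 0.03) went to adjusted p = 0.12 with an estimated correlation and was also lost without control replicate 1 or 2, 2-day replicate 2 or 3 or 7-day replicate 1, with camera adjusted p of 0.068 to 0.095. Of 4 enteroendocrine markers 2 rose, also adjusted over the list alone, Sct from 1.47 to 3.2 CPM and Tac1 from 0.832 to 1.63 CPM; the list was too short for the list test. Chga had 0, 3 and 7 counts over the control, 2-day and 7-day samples and Dclk1 had 19, 8 and 2, so both stayed below the filter.

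Genes of DNA replication and of ribosome production fell modestly at 2 days. Of 26 S phase genes 13 fell, 15 adjusted over the list alone, such as Mcm2 (341 to 232 CPM), Mcm5 (524 to 360 CPM) and E2f1 (33.7 to 25.2 CPM; camera adjusted p = 1.4e-06). Of 26 G2 and M phase genes 1 fell, Ttk (log2FC −0.25), whose call was lost without any single control or 2-day library or 7-day replicate 2 (edgeR adjusted p of 0.0718 to 0.129), and adjusted over the list alone the edgeR count was 0. At unadjusted p under 0.05, 2 rose and 3 fell in edgeR, and limma-voom and DESeq2 called 1 and 2 of them after adjustment (camera adjusted p = 0.41). The proliferation marker Mki67 stood at 323 ± 4.6 and 307 ± 81.6 CPM and did not pass the test; 2-day replicate 3 was at 215.1 CPM, and without it the log2FC turned from −0.07 to 0.13. Of 24 ribosome biogenesis genes 18 fell, 22 adjusted over the list alone, among them Polr1b (151 to 103 CPM) and Nolc1 (408 to 303 CPM; camera adjusted p = 1.7e-08). Of 23 targets of ATF4, a transcription factor of the amino acid stress response, 9 fell and 2 rose (10 and 2 adjusted over the list alone). Slc7a5 fell from 355 to 228 CPM and Psat1 from 677 to 480 CPM, whereas Nupr1 rose from 14.1 to 30.7 CPM (camera adjusted p = 0.0068; adjusted p = 0.5 with an estimated correlation).

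Antimicrobial and inflammatory epithelial genes rose at 2 days, 12 of 14 and 13 adjusted over the list alone (camera adjusted p = 5.4e-10). The chemokine genes Ccl20 (1.1 to 4.45 CPM) and Cxcl1 (2.03 to 5.92 CPM) and the immunoglobulin transporter Pigr (3.02 to 8.56 CPM) were among them. Of 18 fetal or regenerative epithelium genes 11 rose and 2 fell (12 and 2 adjusted over the list alone), with Areg (13.7 to 38.4 CPM), Sprr1a (18.4 to 76.9 CPM) and Clu (117 to 252 CPM) up and Il33 (76.1 to 38.6 CPM) down. That list's camera adjusted p was 0.0015, and its adjusted p was 0.35 with an estimated correlation. Of 9 BMP targets 4 rose and 1 fell, also adjusted over the list alone, with Id1 (6.74 to 20.6 CPM) and Id3 (4.23 to 15.6 CPM) up (camera adjusted p = 0.0064; adjusted p = 0.11 with an estimated correlation). Of 19 fatty acid oxidation genes 7 rose and 1 fell, also adjusted over the list alone, including Pparg (18.3 to 39.2 CPM) and Cpt1a (27.4 to 45.5 CPM). Its camera adjusted p of 0.037 became an adjusted p of 0.48 with an estimated correlation and 0.064 to 0.1 without control replicate 3 or 2-day replicate 1 or 3. Of 20 interferon response genes 3 rose and 1 fell, and 1 rose adjusted over the list alone, Oasl1 from 5.44 to 15.6 CPM. The calls of Irf7, Irf9 and Bst2 were lost without control replicate 2 (edgeR adjusted p = 0.0923, 0.0781 and 0.218) and without several other single libraries. The camera adjusted p of that list was 0.039, or 0.57 with an estimated correlation, and 0.055 to 0.068 without control replicate 1 or 2 or 2-day replicate 1 or 3.

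Camera called none of the remaining lists at 2 days. The fry test, which does not compare a list with other genes, called the Notch, p53, cholesterol synthesis and unfolded protein response lists in the upward direction (fry adjusted p of 0.0014 to 0.011) and of the lists below no other. YAP targets had 2 risers and 7 that fell among 17 (3 and 9 adjusted over the list alone; camera adjusted p = 0.087, or 0.036 without 2-day replicate 2), with F3 up from 32.9 to 65.6 CPM and Crim1 down from 64.6 to 43.3 CPM. Notch pathway genes had 2 up and 3 down among 10 (3 and 4 adjusted over the list alone; median log2FC −0.09, mean 0.09, direction down in camera and up in fry), with Dll1 up from 2.36 to 6.06 CPM and Lfng down from 6.6 to 3.75 CPM. ERK outputs had 2 up and 4 down among 16, also adjusted over the list alone, with Dusp6 up from 104 to 139 CPM. Targets of p53 had 4 up and 1 down among 17 (4 and 2 adjusted over the list alone), with Btg2 up from 11.3 to 16.4 CPM and Trp53inp1 losing its call without control replicate 1 or 2 or 2-day replicate 1 (edgeR adjusted p of 0.0523 to 0.107). Unfolded protein response genes had 3 up among 17 (2 adjusted over the list alone), with Xbp1 up from 64.7 to 92.8 CPM; the calls of Dnajb9 and Hspa5 were lost without 2-day replicate 1, among others (edgeR adjusted p = 0.0573 and 0.152). Cholesterol synthesis genes had 3 up among 21 (6 adjusted over the list alone), Cyp51, Insig1 and Sqle, by 1.16-fold to 1.29-fold, and all of them lost their calls without control replicate 1 or 2 or 2-day replicate 3, among others (edgeR adjusted p of 0.065 to 0.148). Of the 21, DESeq2 called 6 higher and 2 lower, and edgeR had 6 up and 3 down at unadjusted p under 0.05. Glycolysis genes had 1 up, Hk1, and 1 down, Hk2, among 18, both lost without control replicate 3, among others (edgeR adjusted p = 0.0912 and 0.0533), with an edgeR count of 0 adjusted over the list alone; 2 rose and 1 fell at unadjusted p under 0.05, and DESeq2 called 3 and limma-voom 2 over all genes. Of the 24 nuclear respiratory chain genes, edgeR, DESeq2 and limma-voom each called 0, and 1 fell at unadjusted p under 0.05 in edgeR.

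Across the 12535 genes tested, edgeR called 1636 higher and 1333 lower at 2 days, 23.7% of the total, with 419 and 210 beyond a 2-fold change. The number of lower genes fell to 809 without control replicate 2, and a smooth GC trend removed with recentring of the libraries, chosen after the data were seen, gave 1815 higher and 2458 lower. Of the 15 lists called by camera, 8 also passed with an estimated correlation.

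After 7 days the absorptive markers stood far above their control level. Apoa4 (ENSMUSG00000032080, chromosome 9, 46240696 to 46243459, plus strand), an apolipoprotein of fat-absorbing enterocytes, rose from 0.433 ± 0.0965 to 2250 ± 43.6 CPM (log2FC 12.35 ± 0.15, edgeR adjusted p = 6.7e-17). Apoa1 rose 3760-fold to 7900 ± 399 CPM, and sucrase-isomaltase (Sis), a brush border disaccharidase, rose 3120-fold to 893 ± 142 CPM. Alpi rose from 1.2 ± 0.0313 to 1430 ± 151 CPM (10.21 ± 0.15, edgeR adjusted p = 9.2e-17) and Krt20 to 1110 ± 24.9 CPM (8.57 ± 0.17, edgeR adjusted p = 2.2e-15). In the other direction Axin2 fell to 0.658 ± 0.0943 CPM (−6.73 ± 0.13, edgeR adjusted p = 1.5e-15) and Tnfrsf19 (ENSMUSG00000060548, chromosome 14, 60963875 to 61046490, minus strand) from 111 ± 2.62 to 0.0514 ± 0.0192 CPM (−10.94 ± 0.19, edgeR adjusted p = 4.1e-16). Apoa4 in controls and Axin2 and Tnfrsf19 at 7 days had few counts (13, 20 and 18 for Axin2), so their SE are likely too small.

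All 28 enterocyte markers tested rose at 7 days, also adjusted over the list alone, with a median log2FC of 8.29 (camera adjusted p = 2.7e-12). Among them Mttp, which loads lipid onto lipoproteins, rose from 5.96 to 1050 CPM. Several genes had no counts in the controls, and their bounds use 3 counts over the control group. The sulphate transporter Slc13a1 reached 45.2 CPM (at least 1340-fold higher), trehalase (Treh) 37.6 CPM (at least 1110-fold higher) and Ugt2b5 27.6 CPM (at least 826-fold higher). Cyp2d12, Cyp2c40 and Ugt2b38 were at least 397-fold, 364-fold and 324-fold higher; these Ugt2b and Cyp2 genes have close copies, so their counts are uncertain. Apoc3 had 1 control count against 189 CPM at 7 days, a ratio of 16800 (95% counting interval 3010 to 663000), and Fabp1 had 3 against 29.1 CPM, a ratio of 869 (297 to 4220); the intervals cover counting error only. All 3 control counts of Fabp1 came from control replicate 3, without which its fitted log2FC went from 9.58 to 12.72 (8.92 without control replicate 2), and that of Apoc3 went from 13.56 to 15.37 without control replicate 2. All 14 colonocyte markers rose, also adjusted over the list alone, or 13 when scaled by library size only and 12 of 13 without the 100 most abundant genes (median log2FC 6.44, camera adjusted p = 3.6e-06), with Lypd8 at 1810 ± 385 CPM and the gut peptide gene Guca2b from 0.139 to 88.9 CPM.

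Of 17 goblet cell markers 15 rose and 2 fell at 7 days, also adjusted over the list alone. Zg16 rose from 1.7 to 360 CPM, Fcgbp from 18.9 to 2210 CPM and Tff3 from 10.9 to 910 CPM, while Galnt12 and Foxa3, named after their values were seen, fell (log2FC −1.08 and −0.46). The list's camera adjusted p was 8.9e-05, and its adjusted p was 0.052 with an estimated correlation. Of the 6 Paneth cell markers tested 5 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.1). The riser was Guca2b, also on the colonocyte list. Pla2g2a had no counts at 7 days, at most 0.00582 of the control level, and Mmp7 fell from 4.32 to 0.234 CPM. Lyz1 fell to 0.394 ± 0.0747 CPM (edgeR adjusted p = 0.00017). Tuft markers had 2 up and 3 down among 5, or 1 and 3 when scaled by library size only (camera adjusted p = 0.47), with Ptgs1 down to 35.2 CPM. Enteroendocrine markers had 2 up and 1 down among 4, with Sct up from 1.47 to 4.52 CPM and were 1 and 1 when scaled by library size only. The call for Isl1 (log2FC −1.12) was lost without control replicate 1 or 2, 2-day replicate 1 or 3 or 7-day replicate 1 or 2 (edgeR adjusted p of 0.0503 to 0.172), and that for Nts (log2FC 1.02) without control replicate 1 (0.0662) or with library-size scaling (0.166). Both sets of counts were the same adjusted over the list alone.

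Of 19 Wnt targets 18 fell and 1 rose at 7 days, and of 15 crypt-base stem cell markers 13 fell, both also adjusted over the list alone. Wnt targets had a median log2FC of −2.53 and a camera adjusted p of 3.8e-07 (adjusted p = 0.061 with an estimated correlation). Tcf7 fell from 73.1 to 2.93 CPM, Cdca7 from 155 to 17.8 CPM and Sp5 from 25.7 to 0.373 CPM, while Zfp703, named after its value was seen, rose by a log2FC of 0.31; no Wnt target rose with library-size or upper-quartile scaling or without the 100 most abundant genes. Stem cell markers had a camera adjusted p of 3.2e-05, with Lgr5 at 0.886 ± 0.25 CPM. Ascl2 was left with 1 count over the 7-day samples, a ratio to control of 0.000711 (95% counting interval 1.8e-05 to 0.00397). Slc14a1 and Rgcc each kept 3 counts, with ratios of 0.00388 (0.000799 to 0.0114) and 0.00693 (0.00142 to 0.0204). Hunk fell 200-fold from 108 to 0.537 CPM, Dpp6 fell from 13.8 to 0.068 CPM, Ptpro from 7.93 to 0.0617 CPM and Lifr 65.6-fold. Without 7-day replicate 1, fitted log2FC went from −10.03 to −12.07 for Ascl2, −7.84 to −8.77 for Slc14a1 and −7.64 to −8.38 for Dpp6, and Ptpro from −6.84 to −7.48 without 7-day replicate 3. Myc fell 2.39-fold to 85.4 ± 8.03 CPM.

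Cell cycle and ribosome production genes fell as whole lists at 7 days, with the same counts adjusted over the list alone. All 26 S phase genes fell (median log2FC −2.09, camera adjusted p = 1.6e-09), including Mcm4 (217 to 45 CPM), Cdc45 (59.4 to 11.9 CPM) and Uhrf1 (297 to 43.1 CPM). All 26 G2 and M phase genes fell (median log2FC −1.64, camera adjusted p = 9.4e-09), including Ccnb1 (309 to 63.2 CPM) and Foxm1 (104 to 27.7 CPM). Mki67 fell 2.27-fold to 143 ± 13.4 CPM (log2FC −1.18 ± 0.15, edgeR adjusted p = 2.5e-06). All 24 ribosome biogenesis genes fell (median log2FC −1.89, camera adjusted p = 8.4e-09), among them Nop16 (97 to 14.3 CPM), Nop56 (390 to 100 CPM) and Tcof1 (252 to 50.6 CPM).

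Metabolic lists rose at 7 days, with the same counts adjusted over the list alone, but their list calls were lost with an estimated correlation. All 19 fatty acid oxidation genes rose (median log2FC 1.71, camera adjusted p = 3.8e-07; adjusted p = 0.096 with an estimated correlation), with Ehhadh from 8.76 to 127 CPM, Slc25a20 up 7.85-fold and Cpt1a from 27.4 to 190 CPM. Of 21 cholesterol synthesis genes 16 rose and 5 fell, or 12 and 5 when scaled by library size only (camera adjusted p = 0.025; adjusted p = 0.095 with an estimated correlation, and 0.062 in camera with library-size scaling), with Insig1 from 131 to 648 CPM. Of 18 glycolysis genes 15 rose and 2 fell (camera adjusted p = 0.0061; adjusted p = 0.59 with an estimated correlation), with Gpi1 from 497 to 1910 CPM and Ldha from 2260 to 6020 CPM. Of 24 nuclear respiratory chain genes 18 rose and 1 fell (camera adjusted p = 0.0061; adjusted p = 0.59 with an estimated correlation), with Sdhc from 119 to 285 CPM. Scaled by library size only, 11 of these rose and 6 fell, and the camera adjusted p was 0.11. Of 13 respiratory chain genes of the mitochondrial genome 12 rose, with mt-Nd5 from 309 to 1020 CPM and mt-Nd4 from 447 to 1670 CPM (camera adjusted p = 0.0095; adjusted p = 0.59 with an estimated correlation). At 2 days 1 of those 13, mt-Nd2, had fallen (log2FC −0.50; 0 adjusted over the list alone, 2 down at unadjusted p under 0.05 in edgeR, and 1 called by DESeq2 and by limma-voom), and that call was lost without control replicate 2 or 3 or 2-day replicate 1 or 2 (edgeR adjusted p of 0.0747 to 0.152). Mitochondrial transcripts made up 0.957% to 1.38% of the counts in controls, 0.94% to 1.29% at 2 days and 1.6% to 2.36% at 7 days.

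Of 20 interferon response genes 17 rose and 1 fell at 7 days, and all 14 antimicrobial and inflammatory genes rose, both also adjusted over the list alone. Irf7 rose from 2.17 ± 0.313 to 122 ± 50.7 CPM, Ifit1 from 0.169 to 22.6 CPM and Oasl1 from 5.44 to 225 CPM, while Bst2, named after its value was seen at this time, fell (log2FC −0.53). The interferon list had a median log2FC of 2.95 and a camera adjusted p of 3.2e-05 (adjusted p = 0.36 with an estimated correlation). Pigr rose from 3.02 to 312 CPM, Nos2 from 0.0804 to 77.9 CPM and Il18 from 1.03 to 34.8 CPM, on a list with a camera adjusted p of 1.2e-05.

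The other lists were mixed at 7 days and camera called none of them, with the same counts adjusted over the list alone unless stated. The fry test called all 8 lists below except ERK outputs, YAP targets in the downward and the other 6 in the upward direction (fry adjusted p of 5.5e-07 to 0.014). Of 18 fetal or regenerative genes 11 rose and 6 fell, or 8 and 7 when scaled by library size only, with Sprr1a from 18.4 to 577 CPM and Clu from 117 to 817 CPM up (camera adjusted p = 0.29). YAP targets had 7 up and 9 down among 17, or 3 and 10 when scaled by library size only, with Gadd45a up from 3.07 to 15.1 CPM and Ptpn14 down from 98.6 to 28.7 CPM. Notch pathway genes had 5 up and 4 down among 10 (5 and 5 adjusted over the list alone), or 3 and 5 when scaled by library size only, with Dll1 up to 12.9 CPM and Jag2 down from 67.4 to 18.4 CPM. BMP targets had 5 up and 2 down among 9, with Bmp2 up from 3.44 to 47.4 CPM and Bambi down from 6.74 to 1.22 CPM. ERK outputs had 6 up and 9 down among 16, or 3 and 10 both when scaled by library size only and without the 100 most abundant genes, with Dusp6 up to 229 CPM and Etv4 down to 20.7 CPM. Targets of p53 had 8 up and 5 down among 17, or 6 and 9 when scaled by library size only, with the cell cycle inhibitor Cdkn1a up from 20.5 to 211 CPM and Aen down from 58.5 to 16.2 CPM. ATF4 targets had 12 up and 9 down among 23, or 9 and 10 when scaled by library size only. Ddit3 rose from 2.38 to 19 CPM and Ddit4 from 18.9 to 120 CPM, while Psat1 fell from 677 to 130 CPM and Slc7a5 from 355 to 66.7 CPM. Unfolded protein response genes had 7 up and 5 down among 17, or 6 and 9 when scaled by library size only, with Dnajb9 up from 5.98 to 33.8 CPM.

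Across the genome edgeR called 5080 genes higher and 5237 lower at 7 days, 82.3% of those tested, with 2794 and 2451 beyond 2-fold and 1383 and 545 beyond 4-fold. Scaled by library size only, the split was 3675 higher and 6876 lower (34.8% higher against 49.2%), with the median log2FC of all genes moved from −0.03 to −0.43, so directions of small changes are relative to the scaling. Of the 15 lists called by camera, 7 also passed with an estimated correlation.

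**Figure D2:**
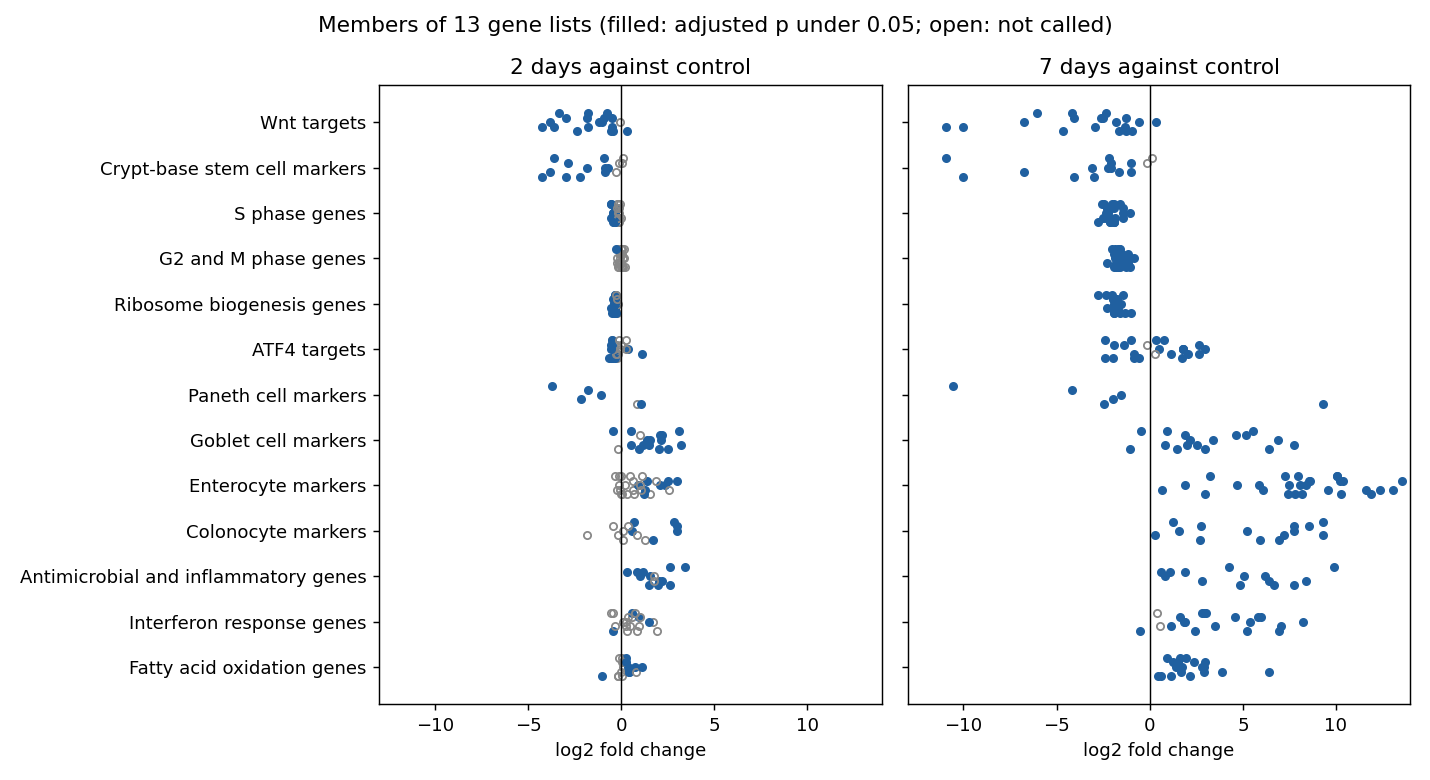
Log2 fold changes against control of the members of 13 gene lists fixed before the data were examined, at 2 days and at 7 days; filled points passed edgeR's adjusted p threshold and open points did not, and the fitted values of genes with 0 counts in a group depend on the prior count. Enterocyte markers have a median of 0.82 at 2 days and 8.29 at 7 days, and S phase genes of −0.29 and −2.09.

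The 7-day samples were also compared directly with the 2-day samples, which asks what changed between these times. Apoa4 rose 3400-fold from 0.657 ± 0.0959 to 2250 ± 43.6 CPM (log2FC 11.73 ± 0.14), Apoc3 rose 3280-fold and Apoa1 1630-fold; the log2FC of Apoc3 went from 11.68 to 13.15 without 2-day replicate 3. Gdpd2 and the glucose-6-phosphatase gene G6pc had no counts at 2 days and were at least 305-fold and 211-fold higher. Alpi rose 205-fold and Krt20 48.1-fold. The largest falls under the rule were Tnfrsf19 (161-fold), Hunk (37.6-fold), Krt6a (21.7-fold), Cdo1 (19-fold) and Cep78 (11.4-fold). Axin2 fell a further 7.66-fold and Lgr5 by a log2FC of −1.15 (edgeR adjusted p = 0.00016). Mki67 fell by a log2FC of −1.11 (edgeR adjusted p = 5.8e-06) and the stem cell and tumour marker Cd44 from 123 to 40.7 CPM.

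Between 2 and 7 days all 28 enterocyte and all 14 colonocyte markers rose, and all 26 S phase, 26 G2 and M phase and 24 ribosome biogenesis genes fell, also adjusted over the list alone. Their camera adjusted p values were 2.4e-13, 3.2e-06, 6.7e-10, 1.4e-09 and 6.4e-09, and these 5 of the 15 called lists also passed with an estimated correlation. The enterocyte median log2FC was 7.57, or 7.36 with genes at 0 in a group set at their bound. Wnt targets had 17 down and 2 up among 19 (camera adjusted p = 4.8e-05; adjusted p = 0.11 with an estimated correlation), and stem cell markers 10 down among 15 (camera adjusted p = 0.0016; adjusted p = 0.061 with an estimated correlation). Interferon response genes had 18 up among 20, such as Oasl1 from 15.6 to 225 CPM (camera adjusted p = 1.8e-05; adjusted p = 0.32 with an estimated correlation). Goblet cell markers had 14 up and 1 down among 17, antimicrobial genes 12 up and 1 down among 14, cholesterol synthesis genes 16 up and 3 down among 21, and fatty acid oxidation genes all 19 up. Their camera adjusted p values were 0.0015, 0.00091, 0.019 and 8.2e-08, and each had an adjusted p of 0.087 with an estimated correlation; the cholesterol call was also lost in camera with library-size scaling (adjusted p = 0.12). Glycolysis genes (15 up, 1 down of 18) and the nuclear (20 up, 1 down of 24) and mitochondrial (12 up of 13) respiratory chain genes had camera adjusted p values of 0.0021, 0.0013 and 0.0022, and adjusted p of 0.6, 0.59 and 0.59 with an estimated correlation. Scaled by library size only, 12 colonocyte markers rose, 14 stem cell markers fell, and the counts up and down were 0 and 17 for Wnt targets, 17 and 1 for interferon response genes, 9 and 2 for goblet cell markers, 9 and 1 for antimicrobial genes, 7 and 5 for cholesterol synthesis, 12 and 3 for glycolysis and 10 and 5 for the nuclear respiratory chain, and 9 mitochondrial respiratory chain genes rose. All the TMM-scaled counts were the same adjusted over the list alone. In all edgeR called 4912 genes higher and 5006 lower, 79.1% of those tested, or 3281 and 7041 when scaled by library size only, which moved the median of all genes to −0.44.

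Most early changes continued. Of the 1636 genes higher at 2 days, 1431 were higher and 101 lower at 7 days, and 1239 rose further between the times while 206 moved back. Of the 1333 lower at 2 days, 1114 were lower and 117 higher at 7 days, and 932 fell further while 224 moved back. The 2545 genes called in the same direction at both times compare with 663 higher and 557 lower for independent lists. Both comparisons use the same controls, so 9 unchanged libraries, controls included, were simulated 20 times, in a form chosen after the values had been seen. In these edgeR called 0 genes at both times, and at unadjusted p under 0.05 a mean of 123 and at most 142 genes in the same direction. Across genes, which are not independent replicates, the log2FC at 2 and 7 days correlated at 0.668 against a simulated 0.486, with a covariance of 0.694 against 0.0285. The 3 controls could not be split into groups of at least 2, so part of the excess may come from the shared controls.

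Markers of cell types other than epithelium were looked for in the same samples, and most were low. Only 5 of 14 fibroblast, 4 of 14 immune and 4 of 12 endothelial markers listed passed the filter. Of 5 fibroblast markers 2 fell at 2 days, Vim from 17.8 to 5.46 CPM and Col1a2 from 0.568 to 0.212 CPM, the latter lost in DESeq2 and without control replicate 1 or 2-day replicate 1 (edgeR adjusted p = 0.0618 and 0.0541; camera adjusted p = 0.43; median log2FC 0.01, mean −0.12). At 7 days 2 rose and 2 fell, with Vim at 0.988 CPM and Tagln from 0.355 to 0.785 CPM, a rise not called with library-size scaling; Acta2 stood at 34.2 ± 3.73, 37.8 ± 4.94 and 29.6 ± 5.73 CPM and did not pass against control. From 2 to 7 days Acta2 fell (log2FC −0.35, edgeR adjusted p = 0.024), a call lost without 2-day replicate 1 (0.138) or 7-day replicate 3 (0.118). The other fibroblast riser at 7 days, Pdgfrb, went from 1 count over the controls to 0.504 CPM, a ratio of 45 (95% counting interval 7.62 to 1820), with a fitted log2FC of 5.04, or 6.84 without control replicate 2. Of 4 immune markers 1 rose at 2 days and 4 at 7 days, with Cd14 at 9.06, 19.5 and 21 CPM and Cd68 at 1.11, 1.28 and 3.36 CPM. Csf1r went from 2 counts over the controls to 0.956 CPM at 7 days, a ratio of 42.1 (11.3 to 354), with a fitted log2FC of 5.15, or 4.52 without control replicate 2. The call for Laptm5 at 7 days, from 0.167 to 0.59 CPM (log2FC 1.80, from 0.80 without 7-day replicate 1 to 2.51 without control replicate 1), was lost without control replicate 2 or 3, 2-day replicate 2 or 7-day replicate 1 (edgeR adjusted p of 0.065 to 0.327) and, among others, with library-size scaling (0.116) and in limma-voom (0.111). Of 4 endothelial markers 1 fell at 2 days and 2 at 7 days, Esam from 15.2 to 5.28 and then 1.73 CPM and Egfl7 from 7.96 to 4.41 CPM at 7 days. Each of these counts was the same adjusted over the list alone, and the immune and endothelial lists were too short for the list test.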

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

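The tests of doxycycline, of shared globin reads, of GC content and of the 100 most abundant genes were chosen only after the result was seen. No group had 4 or more samples, so single outlying samples were not tested for.

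Counted over all tested genes, edgeR called 218 in opposite directions at 2 and 7 days against control. All of them also differed between these times, which opposite calls against the same controls nearly imply. The count includes near-identical copies, such as Gm21293 and Gm8764 (both log2FC 0.43 and then −1.18), so it is not of 218 separate changes. Among genes of the lists, those that were up at 2 days and down at 7 days had these log2FC from 2 to 7 days: Reg4 −3.53, Atoh8 −1.56, Ankrd1 −1.52, Ly6c1 −1.40, Apcdd1 −1.29, Plk2 −1.29, Anxa3 −0.58 and Spred1 −0.57. Reg4 went from a log2FC of 1.09 at 2 days to −2.43 at 7 days. Those down first and up later were Vldlr 2.34, Acot1 2.15, Ccn2 1.58 and mt-Nd2 1.46. Vldlr went from −0.53 to 1.81 and Ccn2 from −0.31 to 1.27.

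Most tested genes were called at 7 days, 10317 of 12535. Without the 100 most abundant genes there were 10264 calls, so these genes do not make up the number. It was also 10551 with library-size scaling, so the total says little on how abundant genes set the scale. Without them 42.4% of the called genes were higher (49.2% with them), and the median log2FC was −0.21 (−0.03). Thinning to the smallest library gave 10131 calls, but totals of 24143589 to 32277040 differed too little to test depth well. A GC trend is argued against by 10570 calls after its removal. That the change in state that Apc restoration or doxycycline removal brings may reach most genes stays a hypothesis, since scaling still sets the direction of small changes. Time in culture is not separated from these. Of the 10 splits of the 6 samples in each comparison, only 1, the real one, gave its 2969, 10317 and 9918 edgeR calls. The highest other split gave 0 calls in each, with 735, 321 and 106 genes at unadjusted p under 0.05, but 10 splits are too few for a share under 0.05. Each other split also mixed the 2 groups, which puts a large group difference into the spread. Few calls would follow from that whatever the cause of the difference.

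Of 23 ATF4 targets 9 fell and 2 rose at 2 days (camera adjusted p = 0.0068; adjusted p = 0.5 with an estimated correlation). The absence of doxycycline, an antibiotic that acts on mitochondrial translation, may account for the fall of these 9, as may Apc restoration; the design confounds these causes. The 9 members called lower at 2 days had a median log2FC of −1.37 at 7 days against control and 8 were called lower, as were 1106 of the 1324 other genes lower at 2 days (median −1.32; one-sided Fisher p = 0.55), so their fall at 7 days decides nothing on doxycycline. From 2 to 7 days they fell further, with a median of −0.87, 8 of 9 below 0 (one-sided exact sign test p = 0.0195) and 7 called. That test takes genes as independent, although the estimated correlation within the list was 0.43. Such a fall was also common, since 932 of the 1333 genes lower at 2 days fell further. The whole list had 12 up and 8 down among 23 from 2 to 7 days. An effect that acts alike at both times would not by itself give the further fall, but this decides nothing on doxycycline. Both causes stay open for the 2-day fall, and time in culture is not separated from them.

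The beta-globin genes Hbb-bs and Hbb-bh1 stood at 12.1 and 8.96 CPM in controls, 0.687 and 0.804 CPM at 2 days and 1.06 and 1 CPM at 7 days. Red cell RNA is argued against: alpha-globin counts were 1.49% of Hbb-bs counts (16 against 1072, upper exact 95% limit 2.44%), and 1 of 9 erythroid markers, Car2 at 22.5 CPM, which intestinal epithelium also expresses, reached 1 CPM. The 16 counts sum Hba-a1 and Hba-a2, which had the same 8 counts each in controls, so the same reads may be counted for both. The share would then be lower and its limit not exact. Hbb-bh1 counts were 72.9% to 76.2% of Hbb-bs counts in the controls, which decides nothing on reads shared between these genes, since sharing would also give a steady share. The share was not the same in the other groups, with 76 counts against 65 at 2 days and 76 against 80 at 7 days. These counts are few and reads may be shared in part, so that explanation stays open. The other beta-globin genes Hbb-bt, Hbb-y and Hbb-bh2 had 6, 5 and 0 counts over the controls. These values do not decide on sharing between Hbb-bs and Hbb-bh1. Transcription of Hbb-bs or Hbb-bh1 in the control cells themselves also stays open as a hypothesis, not tested further.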

How the results depend on the processing

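The run without the 100 most abundant genes and both GC corrections were chosen after seeing the data, the GC form that keeps each library's centre after the other form. Of gene results, 5153 kept direction and side of the threshold, 151 lost a call, 73 gained one and 11 turned over the alternatives; with single samples left out these were 3418, 79, 19 and 15. The cause was not tested unless stated.

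Testing against a log2 fold change of 1 with glmTreat, which asks for larger changes, gave 170 higher and 94 lower genes at 2 days, 2354 and 1816 at 7 days, 1977 and 1385 between them, and 252 at both times. The estimated correlation left 8, 7 and 5 of 15 lists, and fry, which asks another question, called 25 at 7 days. Removing the GC trend with recentring gave 2458 lower genes at 2 days (1333 in the main analysis), and keeping the centre 1921.

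Of all called genes, 57 at 7 days and 84 from 2 to 7 days were called the other way with library-size scaling, 29 and 20 with GC recentred, and 2 and 2 with the GC trend removed. The named genes whose log2FC turned were not called in the main analysis. From 2 to 7 days Cd14, at 0.10, gave −0.32 with library-size scaling, −0.02 with upper-quartile factors, −0.11 without the 100 most abundant genes, and −0.02 and, recentred, −0.21 with the GC trend removed. From 2 to 7 days Ptgs1 gave 0.01 with DESeq2 size factors and 0 in DESeq2. At 2 days Tagln gave −0.06 thinned and −0.01 with GC recentred, and Fabp1 0.27 in limma-voom. Removing the GC trend gave Tac1 0.11 at 7 days.

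Leaving out 1 sample, counts at 2 days ranged from 1184 to 1781 higher and 809 to 1517 lower (809 without control replicate 2), at 7 days 4892 to 5140 and 4990 to 5279, and between them 4730 to 4995 and 4730 to 5068. Both-time calls ranged from 1737 to 2791 and lists at 2 days from 12 to 16. Single genes that turned at 2 days ranged from −0.40 to 0.18 (Isl1), −0.35 to 0.33 (Tagln), −0.69 to 0.46 (Csf1r), −0.19 to 0.04 (Trp53), −0.88 to 3.07 (Fabp1), −0.23 to 0.13 (Mki67) and −0.42 to 0.69 (Nts). At 7 days Tac1 ranged from −0.17 to 0.09, and from 2 to 7 days Ptgs1 from −0.07 to 0.04.

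The replicate block called 4039, 10667 and 10308 genes (2969, 10317 and 9918 without). Correlations of deviations between same-numbered samples were −0.13 to 0.48, 5 of 9 above 0.1, and 6 of 9 samples correlated best with their own number. In each group number 1 also had the lowest and number 3 the highest mitochondrial share and TMM factor. This hints at a shared effect of the number, but not every pair was above 0.1 and the labels name no shared culture or day, so the block was not made the main model. DESeq2 called 3010, 10358 and 9880 genes and limma-voom 2969, 10305 and 9917. Depth limits genes such as Fabp1, Chga and Dclk1, which had few counts.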

Other observations

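The gene families below and their members were chosen after the data had been seen, by shared symbol starts, with 816 one-sided Fisher's exact tests in all, and members of a family are not independent.

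Of 45 cytochrome P450 (Cyp) genes 41 rose and 3 fell at 7 days, with a median log2FC of 6.05 (Fisher adjusted p = 6.2e-10), such as Cyp3a13 from 20.2 to 629 CPM and Cyp4f14 from 1.54 to 807 CPM. All 13 Ugt and all 9 Ces genes tested rose, such as Ugt1a1 from 0.26 to 111 CPM and Ces2e from 0.373 to 302 CPM; close copies in these families make their counts uncertain. Of 241 solute carrier (Slc) genes 147 rose and 53 fell (Fisher adjusted p = 1.6e-08), or 115 and 79 when scaled by library size only. The sodium-glucose transporter Slc5a1 went from 0.298 CPM in controls to 75.8 CPM. Among single genes, the transcription factor Hnf4a rose from 242 to 490 and 1450 CPM and Hnf4g from 3.44 to 7.1 and 97.9 CPM, and Cdx2 stood at 171, 178 and 165 CPM and did not pass the test. The claudin Cldn15, a tight junction protein of the gut, rose from 4.52 to 16.2 and 251 CPM.

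At 7 days 43 of 48 genes of the large mitochondrial ribosome subunit (Mrpl) fell, with a median log2FC of −0.60 (Fisher adjusted p = 1.6e-09), as did 23 of 29 of the small subunit (Mrps). Mrpl19 fell from 70.1 to 27.2 CPM and Mrps5 from 99.1 to 51 CPM. Nuclear pore genes (Nup, 19 of 20) and RNA polymerase subunits (Polr, 25 of 28) also fell. At 2 days 37 of 58 histone (Hist) genes rose (Fisher adjusted p = 2.2e-16), such as Hist1h1c from 92.3 to 161 CPM. Of these 37, 16 were higher and 17 lower than in controls at 7 days, such as Hist1h4i with a log2FC of 0.51 and then −1.54, or 16 and 20 when scaled by library size only. Many have near-identical copies, so these counts are uncertain. The libraries were made from poly(A) RNA, which misses transcripts without a poly(A) tail, so these counts do not measure all histone RNA.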
